A study of Drosophila melanogaster with 3 samples.

How the data were processed

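Embryos of 0 to 24 hours expressing a C-terminal fusion of CG12942 to green fluorescent protein were used for ChIP-seq with an antibody against the tag, per the labels. Chromatin was fragmented by sonication, per the labels. The 3 samples are biological replicates of 1 group, and their replicate numbers were taken from the labels. The biosample differs between the 3, per the labels.

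The values are 10 narrowPeak lists deposited by the authors: 3 replicate lists, 1 pooled list and 1 optimal list on each of dm6 and dm3. Per the file listings deposited with the libraries, each replicate list was called on 1 library against a control alignment, the pooled list on the 3 alignments together, and the optimal dm6 list was derived from the replicate and pooled lists by IDR, a procedure that keeps peaks ranked alike between replicates. The optimal dm3 list is recorded there as derived from the pooled list and that of replicate 3. The aligner, the peak caller and their versions are not given in the sources used here. The strength of a peak is the signal value written by the authors' peak caller, whose scale depends on depth, so it was used only to describe and rank peaks within a list. The lists also carry the −log10 of a q value deposited by the authors, which reaches the same highest value in many peaks and was not used for ranking. The replicate lists are relaxed lists that include background, 3 of them with exactly 30000 peaks. The depth of the libraries is unknown, so no interval based on read counts is given. Of the optimal dm6 peaks, 22 share their start and end with another and differ in the summit. Signal tracks and the control library were not analysed here.

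The dm6 lists were set against the genome sequence and the Ensembl release 115 annotation of the same assembly. Every dm6 peak on the 6 arms 2L, 2R, 3L, 3R, 4 and X ended within the length of its arm. The dm3 lists were used only for counts, shares per arm and overlap among themselves, and no coordinates were converted. These dm3 values include peaks outside the 6 arms, and only the shift test of the dm3 overlap was limited to the arms. Coordinates are 1-based.

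Peaks were ranked by signal, and the top 3844 of each replicate, the size of the optimal dm6 set, were compared. Summits within 200 bp were called matched. A promoter summit lay within 500 bp of the TSS of a protein-coding transcript. Every summit was put in the first class that applied of promoter, 5' UTR, coding sequence, 3' UTR, exon of a noncoding gene, intron and intergenic. Overlap and class shares were tested with 1000 circular shifts along each arm. Gene lists, head-to-head genes and arms were tested with Fisher's exact test, two-sided, against all other protein-coding genes of the 6 arms. The 30 gene lists were symbol patterns, and a few lists share genes. The 15 motifs were fixed consensus sequences searched on both strands within 50 bp of the summit and in a window of equal width centred 400 bp away, and compared with the exact McNemar test. A further control used promoters of genes without a peak and with no optimal summit within 1000 bp, at the distances from the TSS seen at promoter summits. All 7-mers were ranked on arms 2L, 3L and X, and the 10 with the smallest p were tested again on 2R, 3R and 4. The Benjamini-Hochberg adjustment was used over classes, lists, motifs, 7-mers and the 2 arm contrasts.

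The design, the lists, the motifs and 57 alternative settings were fixed before the data were examined, and 3 settings were added later. For classes, promoters, lists, arms, motifs and k-mers, leaving out a replicate meant taking the top 3844 peaks of one remaining replicate that matched the top 3844 of the other, in place of the optimal set. Genes were named by a rule fixed at the same time. It takes the genes at the 25 strongest promoter peaks and the 5 strongest other peaks found in the top 3844 of all replicates, up to 4 bound members of each list past adjusted 0.05 and of the ribosomal, insulator and Hox lists, and CG12942. Other genes are named where a count was 5 or fewer.

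The statistics were tested on simulated data. With 40% of 3844 summits planted at promoters, 47.1% were found there, and with 0% planted 11.1% (permutation p = 0.77). With 70% of 3844 summits planted as shared, 70.3% were matched. Of 100 planted lists 94 passed an unadjusted threshold of 0.05, and of 100 lists without an effect 4, over 13945 genes. For the lists, genes were drawn as bound independently of each other, so summits shared by neighbouring genes were not simulated. A 7-mer planted in 417 of 3844 peaks ranked 1, and the 7 other 7-mers that passed on the test arms each shared 5 bases in a row with it. These simulated summits lay at random positions, so a difference in GC between summits and flanks, as in the data, was not simulated.

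The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.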

Results

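The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) from whole Drosophila melanogaster embryos collected over 0 to 24 hours of development, sexes mixed. The flies carried a transgene that fuses green fluorescent protein to the C terminus of CG12942, and the fusion protein was precipitated with an antibody against the fluorescent protein. CG12942 has no given name in the annotation used here. The samples form 1 group of 3 biological replicates, each from a biosample of its own. No library of another condition, and no control library, was analysed here, so the comparisons below set genomic regions and gene groups against each other within this group. The measurements are the authors' peak lists, with 30000, 30000 and 27870 peaks on dm6 in replicates 1, 2 and 3, and 3844 peaks in the authors' optimal set. Read totals are not given in the sources used here, so the depth of each library is unknown.

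The 25 strongest promoter peaks of the optimal set found in every replicate lay at genes of many different functions. The strongest was at CG14100 (FBgn0036889; dm6 3L, 19590416 to 19590813), where the summit lay upstream of the transcription start site (TSS) and the authors' peak signal was 1896.9. This peak ranked 1 in each of the 3 replicates. The next, ranking 2 in each replicate, lay at Ugalt, which encodes a UDP-galactose transporter (X, 2703686 to 2704093, signal 1623, 45 bp upstream of the TSS). The peak at px (plexus, 2R, 22514107 to 22514504) had a signal of 1209. Several of the strongest peaks lay within 500 bp of the TSSs of a pair of genes in head-to-head orientation. Examples are Chro, which encodes the chromatin protein Chromator, with Ssl1 (signal 1182), Tcs5 with CHMP2B (signal 1157.5), Art3 with mRpS10 (1155), CG5611 with Mtl (1049), CG8320 with Pex11ab (993), Shc with Atat (970.5), CenG1A with mRpS23 (902), CG9147 with Fbw5 (869), CG5098 with CG5757 (835) and Pal1 with Pdrg1 (825). Peaks at single promoters included mRpL41, a mitochondrial ribosomal protein gene (1162), CG1888 (1147), ph-p, which encodes the Polycomb group protein Polyhomeotic proximal (1105), PNPase, which encodes polynucleotide phosphorylase (1026), GstE13 (873), eIF6 (837), gish (833), larp (803), Tina-1 (768), Rtnl1 (762), Sox14 (742) and CG18549 (738). Of the 25, the Chro, CG8320, PNPase and GstE13 summits lay 104, 105, 78 and 73 bp downstream of the nearest TSS. The CG9147 summit lay at 0 bp from it, and the ph-p summit 491 bp upstream. Each of the 25 peaks was within the top 49 of every replicate.

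The strongest peaks away from promoters were found at cbt, CG11050, CG13323, Lk6 and HmgZ. The strongest of them (2L, 480878 to 481299, signal 1387) lay in an intron of ush, 1402 bp upstream of the TSS of cbt, which encodes the transcription factor Cabut, and ranked 4, 3 and 3 in the 3 replicates. The peak in CG11050 was intronic (2L, 6612490 to 6612913, signal 1281), and so was the one in Lk6, a protein kinase gene (3R, 11760869 to 11761244, signal 1116). The peak nearest to CG13323 was intergenic, 11907 bp downstream of that gene's TSS (2R, 13035159 to 13035535, signal 1124). The peak in the HmgZ gene lay in an intron, 531 bp upstream of its nearest TSS (signal 960).

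The 3 replicates placed their strongest peaks at the same positions far more often than shifted peaks did. Among the top 3844 peaks of each replicate, 72.4% of summits in replicates 1 and 2, 72.8% in replicates 1 and 3 and 77.4% in replicates 2 and 3 lay within 200 bp of a summit of the other, a mean of 74.2% ± 2.82 (SD over 3 pairs). Shifting 1 replicate's summits along each chromosome arm gave 1.13% on average for replicates 1 and 2 and 1.79% at most (circular shift, one-sided permutation p = 0.001 for each pair, the smallest that 1000 shifts can give). Of the 3844 optimal peaks, 2441 (63.5%) were matched in the top 3844 of all 3 replicates, 1018 (26.5%) in 2, 365 (9.50%) in 1 and 20 (0.520%) in none. The share matched in all 3 was 99.6% in the strongest of 4 equal parts of the optimal peaks and 8.64% in the weakest. Across optimal peaks the signals of the replicates correlated with a Spearman rho of 0.665, 0.660 and 0.751 for replicates 1 and 2, 1 and 3, and 2 and 3, and with a Pearson r of 0.736, 0.725 and 0.803 on log2 signal (permutation p of rho = 1.00e-05 for each, the smallest that 100000 permutations can give). These correlations are across peaks, which are not independent replicates, and the set was chosen by the authors for agreement between replicates.

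Peak summits were concentrated at the promoters of protein-coding genes. A summit lay within 500 bp of such a TSS for 2008 of the 3844 optimal peaks (52.2%), against 11.5% of shifted summits, a 4.56-fold difference (circular shift, one-sided permutation p = 0.001, the smallest possible). The top 3844 peaks of the replicates gave 52.3% ± 0.863 (SD, n = 3). Of the 2008 promoter summits, 1740 (86.7%) lay upstream of the nearest TSS and the median position was 106 bp upstream. Introns held 1257 summits (32.7%, against 39.9% of shifted summits) and intergenic sequence 466 (12.1%, against 27.9%). Coding sequence outside promoters held 5 summits (0.130%, against 13.9%), which lay in otp, Pde1c, klar, CG31259 and Snx27 and were named after their values were seen. The 3' UTRs held 21 summits (0.546%, against 4.50%) and 5' UTRs 17 (0.442%, against 0.793%). Of the 7 classes, 6 differed from shifted summits (two-sided permutation, adjusted p = 0.0028, or 0.021 for 5' UTRs). Exons of noncoding genes, with 70 summits (1.82%, against 1.58%), did not pass (permutation, adjusted p = 0.32). Shifted summits can land where few reads can be placed, which was not measured.

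**Figure D1:**
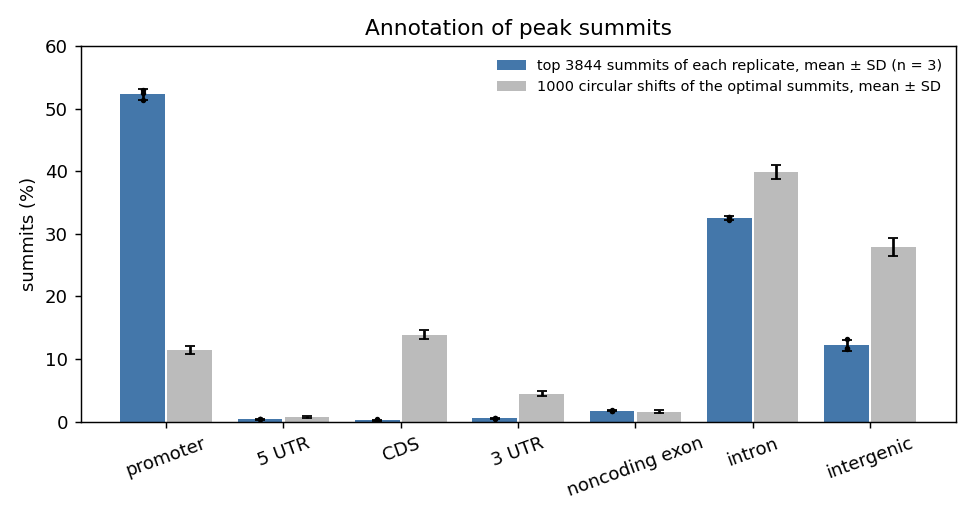
The vertical axis gives the percent of summits in each annotation class on the horizontal axis. Blue bars are the mean and SD of the top 3844 summits of the 3 replicates, with a point per replicate, and grey bars the mean and SD of 1000 circular shifts of the optimal summits. Promoters hold 52.3% of the replicates' summits and 11.5% of shifted summits, and coding sequence (CDS) holds 0.225% and 13.9%.

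Stronger peaks were more often at promoters. Promoters held 314 of the 481 strongest optimal peaks (65.3%, 95% Wilson interval 60.9 to 69.4) and 200 of the 480 weakest (41.7%, 37.3 to 46.1). Within each replicate's top 3844, promoter peaks had a median signal percentile 10.5 ± 2.64 points above that of other peaks (SD, n = 3), with 7.47, 12.3 and 11.7 points in replicates 1, 2 and 3. The exact sign permutation test over 3 replicates gave a two-sided p of 0.25, the smallest it allows. The difference fell to 4.81 points among peaks matching the strongest 1922 optimal peaks, a set chosen by signal itself, and was 8.27 among those matched in all replicates.

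**Figure D2:**
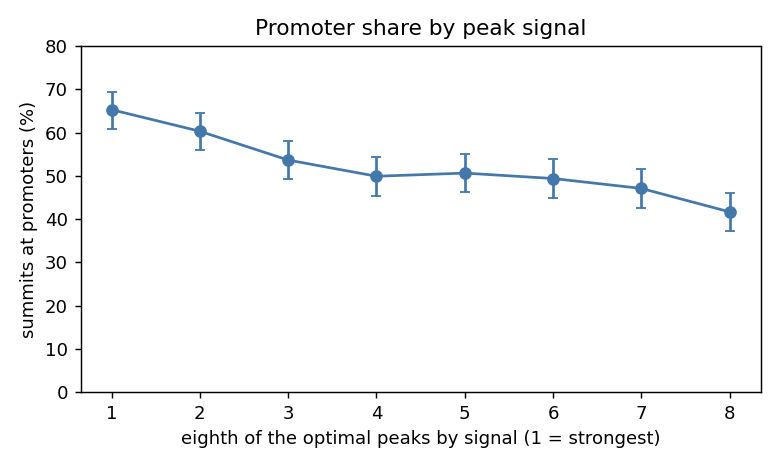
Points give the percent of optimal peaks with their summit at a promoter (vertical axis) in each eighth of the optimal peaks ordered by the authors' signal (horizontal axis, strongest at the left), with 95% Wilson intervals. The share is 65.3% among the strongest and 41.7% among the weakest.

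Cytoplasmic ribosomal protein genes had promoter peaks more often than any other list fixed before the data were examined, and chemoreceptor, cuticle protein and digestive protease genes had 1 or none. In all, 2674 of the 13945 protein-coding genes on the 6 chromosome arms (19.2%) had an optimal summit within 500 bp of a TSS, and 18.9% ± 0.288 (SD, n = 3) had one in the replicates' top 3844. Among ribosomal protein genes the count was 57 of 92 (62.0%, odds ratio 6.99, Fisher's exact test, two-sided, adjusted exact p = 5.52e-18), with 61.6% ± 4.12 in the replicates (SD, n = 3). RpS27 (signal 482), RpL7 (473), RpL34b (449) and RpL23A (399) had the strongest peaks, each found in 3 replicates. Mitochondrial ribosomal protein genes had 26 of 73 (35.6%, odds ratio 2.34, adjusted exact p = 0.00436), led by mRpL41, mRpS10, mRpS23 and mRpL23 (signal 677). The subunit genes of RNA polymerase II had 7 of 13 (53.8%, adjusted exact p = 0.0149), with Polr2B (360), Polr2H (342), Polr2F (268) and Polr2J (234). The aminoacyl-tRNA synthetase genes had 13 of 32 (40.6%, adjusted exact p = 0.0149), with SerRS (322), IleRS (298), ThrRS (251) and AspRS (121).

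Regulators of chromatin and of the cell cycle also had promoter peaks more often than other genes. Genes of insulator and architectural proteins had 12 of 24 (odds ratio 4.23, adjusted exact p = 0.0039), with Chro, Cp190 (signal 450), M1BP (289) and row (233), and this list includes CG12942 itself. Polycomb and trithorax group genes had 13 of 32 (40.6%, odds ratio 2.89, adjusted exact p = 0.0149), with ph-p, brm (509), E(z) (337) and Sfmbt (199). Cell cycle genes had 13 of 33 (39.4%, odds ratio 2.75, adjusted exact p = 0.0163), with Dp (291), tum (234), mei-41 (225) and CycE (178). None of the list tests was adjusted for head-to-head promoters, whose genes had promoter peaks more often than other genes (40.6% against 11.1%). Gene function and promoter arrangement were therefore not told apart. Some summits, as at M1BP and mRpS23, lay nearer to the TSS of a head-to-head partner than to that of the list gene. Of the 7 lists above other genes, ribosomal proteins alone passed the threshold under each of the 9 alternatives. The synthetase list passed under 4 of 9 and gave an odds ratio of 0.803 among the strongest 1922 peaks, and the polymerase and Polycomb lists passed under 5 of 9. Leaving out a replicate also replaced the optimal set, by the 2979, 2797 and 2784 peaks shared by the top 3844 of the other replicates (without replicates 1, 2 and 3), so a lost call cannot be put down to the replicate alone. In these sets the polymerase list did not pass in any case (adjusted exact p of 0.0982, 0.0892 and 0.0945) and nor did the synthetase list (0.496, 0.323 and 0.117). The insulator list did not pass without replicate 1 (0.0982) or 3 (0.171), the Polycomb list without replicate 2 (0.1) or 3 (0.0656), and the mitochondrial ribosomal list without replicate 2 (adjusted exact p = 0.1). Among peaks matched in all replicates the mitochondrial ribosomal, polymerase, insulator, Polycomb and synthetase lists did not pass (adjusted exact p of 0.0681, 0.0681, 0.0821, 0.0821 and 0.547), and among the strongest 1922 peaks the cell cycle, Polycomb and synthetase lists did not (0.118, 0.198 and 1).

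Chemoreceptor, cuticle, digestive protease, male germline, antimicrobial peptide and histone genes had promoter peaks less often than other genes. Of 179 chemoreceptor genes, 1 had a promoter peak (Ir60e, signal 83.1, adjusted exact p = 3.20e-14), and of 121 cuticle protein genes 0 (adjusted exact p = 8.32e-11). Digestive protease genes had 0 of 32 (adjusted exact p = 0.00882) and male germline genes 1 of 46 (Mst85C, signal 100.9, adjusted exact p = 0.0047). The protease list did not pass among the strongest 1922 peaks or among peaks matched in all replicates (adjusted exact p of 0.118 and 0.0641), nor did the germline list with promoter clusters counted once (0.0677). The antimicrobial peptide list had 1 of 35 (adjusted exact p = 0.0204), and that gene, Droj2, is a co-chaperone gene caught by the symbol pattern. This list did not pass under 4 of 9 alternatives, among them without replicate 3 (adjusted exact p = 0.131). Histone genes had 1 of 116, the variant gene His2Av (signal 257, adjusted exact p = 5.36e-09). With promoter clusters counted once the histone list held 74 entries and still passed (adjusted exact p = 3.96e-04). Whether reads can be placed at each histone gene was not measured, so missing peaks there need not mean missing binding.

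The other 17 lists did not pass the threshold. Among them were the proteasome with 9 of 48 genes (18.8%, adjusted exact p = 1), the respiratory chain with 20 of 87 (23.0%, 0.446), translation factors with 15 of 52 (28.8%, 0.148), the nuclear pore with 7 of 21 (33.3%, 0.17), the vacuolar ATPase with 9 of 33 (27.3%, 0.395), the spliceosome with 7 of 25 (28.0%, 0.416), DNA replication with 9 of 34 (26.5%, 0.395) and the chaperonin CCT with 2 of 8 (CCT3 and CCT8, adjusted exact p = 0.719). A partial list of 16 zinc finger genes with a ZAD domain had 6 (37.5%, adjusted exact p = 0.17), CG12942 among them. Developmental genes were represented by 1 of 12 Hox complex genes (bcd, signal 153, adjusted exact p = 0.579), 1 of 29 segmentation genes (nkd, adjusted exact p = 0.066), 8 of 36 neurogenic and proneural genes (22.2%, 0.719) and 11 of 47 signalling genes (23.4%, 0.573). Muscle structure genes had 4 of 27 (Act87E, Msp300, Tm1 and sls, adjusted exact p = 0.834), synaptic genes 2 of 37 (Nrg and Nrx-1, adjusted exact p = 0.0685), heat shock genes 6 of 25 (24.0%, 0.703) and chorion and vitelline genes 0 of 10 (adjusted exact p = 0.356). Of these 17 lists, 5 passed under an alternative setting. With promoter clusters counted once these were translation factors, the nuclear pore and the ZAD list, all above other genes (adjusted exact p of 0.047, 0.03 and 0.048), and translation factors also passed with a window of 250 bp (0.028). With a window of 1000 bp signalling genes passed above other genes and segmentation genes below them (adjusted exact p of 0.043 and 0.0276).

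**Figure D3:**
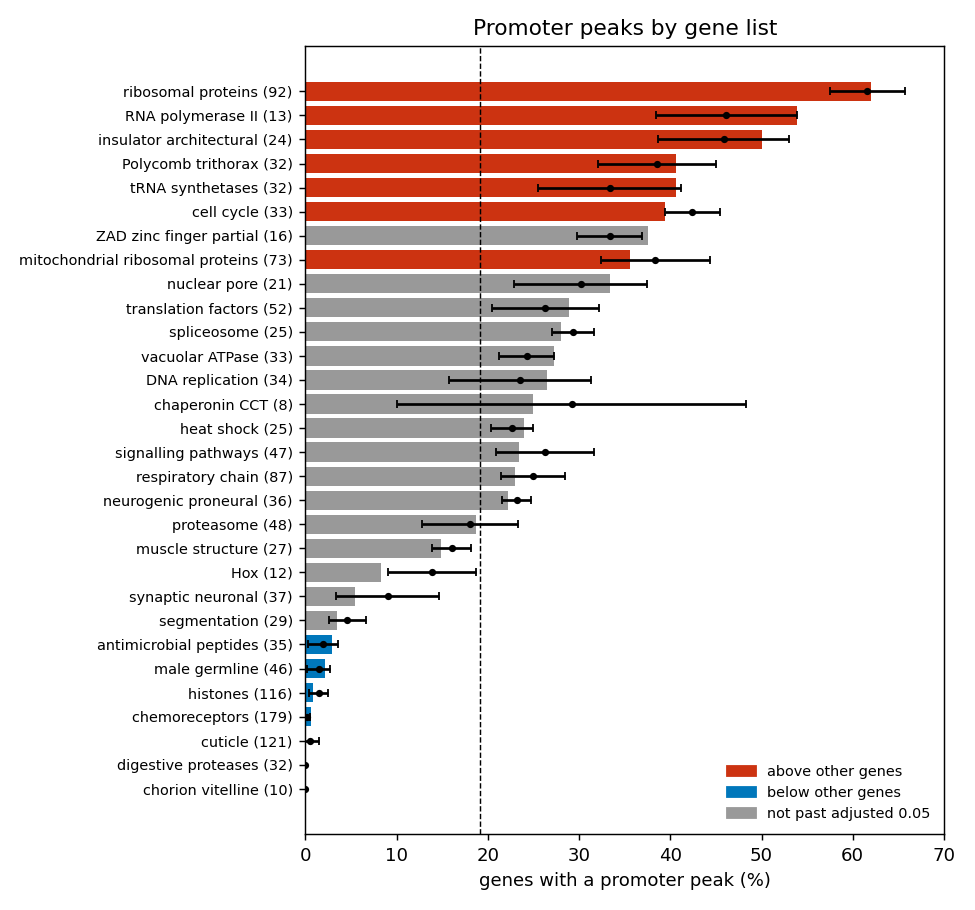
Bars give the percent of each list's genes with an optimal summit within 500 bp of a TSS (horizontal axis), with the number of genes in brackets, and points with lines give the mean and SD over the top 3844 peaks of the 3 replicates. The dashed line marks the 19.2% of all protein-coding genes. Ribosomal proteins reach 62.0%, and the cuticle and digestive protease lists, both below other genes, stand at 0.

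Genes sharing a head-to-head promoter with a neighbour were bound more often than other genes. Of 3815 genes with a TSS within 500 bp of an oppositely directed one, 1547 (40.6%) had a promoter peak, against 1127 of 10130 other genes (11.1%, odds ratio 5.45, Fisher's exact test, two-sided, p = 1.49e-307). The replicates gave 39.2% ± 0.342 and 11.2% ± 0.268 (SD, n = 3). A single summit can count for both genes of a pair. With each pair counted once, a setting chosen after the data were seen, 778 of 1850 pairs had a peak (42.1%, odds ratio 5.80). These include pairs with a peak at a single gene, and both genes were bound in 717 pairs (38.8%). A pair also offers more TSSs to a summit than a single gene does, which was not adjusted for.

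X-linked genes had promoter peaks less often than autosomal genes. The count was 360 of 2196 genes on X (16.4%) against 2302 of 11669 on arms 2L, 2R, 3L and 3R (19.7%, odds ratio 0.798, Fisher's exact test, two-sided, adjusted exact p = 4.97e-04), and the replicates gave 16.2% ± 1.27 and 19.4% ± 0.222 (SD, n = 3). Chromosome 4 had 12 of 80 genes (15.0%, odds ratio 0.718, adjusted exact p = 0.326), with 14.2% ± 6.88 in the replicates. Its odds ratio was 0.242 (adjusted exact p = 0.00518) among peaks matched in all 3 replicates, 0.296 without replicate 2 and 0.292 without replicate 3, all past the threshold, and 1.00 without replicate 1. The last 3 sets are peaks shared by the top 3844 of 2 replicates, not the optimal set with a replicate removed. The embryos were of mixed sex, and neither the copy number of X nor the share of head-to-head genes on each arm was adjusted for in these comparisons.

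Several sequence motifs of promoter and insulator proteins were found at summits more often than 400 bp away, where the sequence was richer in GC (44.3% against 34.1% at summits). Such a difference by itself makes motifs rich in A and T more frequent at summits and motifs rich in G and C less frequent. The comparison with the flank therefore cannot separate AT-rich motifs such as the TATA box, motif 6 and the homeodomain core from base composition. The DRE (TATCGATA), bound by DREF and BEAF-32, was within 50 bp of 71 summits and in 15 flank windows of equal width (exact McNemar test, two-sided, adjusted exact p = 3.05e-09). Core promoter motif 7 was in 119 and 46 (adjusted exact p = 2.31e-08), the ZIPIC motif in 63 and 20 (adjusted exact p = 7.29e-06), the TATA box in 92 and 39 (adjusted exact p = 1.04e-05), motif 1 of M1BP in 23 and 3 (adjusted exact p = 1.89e-04), motif 6 in 63 and 32 (adjusted exact p = 0.00361), the Su(Hw) motif in 20 and 5 (adjusted exact p = 0.0068), the CTCF motif in 26 and 9 (adjusted exact p = 0.00898) and the homeodomain core in 1090 and 794 (adjusted exact p = 2.33e-13). The GAGA motif bound by Trl was in fewer summits than flanks (42 and 116, adjusted exact p = 7.61e-09). The initiator (summits 301, flanks 350, adjusted exact p = 0.0663), the Zelda (18 and 20, 0.871), Pho (54 and 62, 0.553), Twist (38 and 46, 0.507) and E-box (16 and 10, 0.409) motifs did not pass. Against promoters of genes without a peak, motif 7 (odds ratio 2.70, adjusted exact p = 3.58e-13), ZIPIC (3.37, 3.71e-09) and DRE (1.43, 0.0269) were more frequent at promoter summits, and the TATA box (0.607, 0.00352), the initiator (0.623, 1.74e-07), GAGA (0.480, 0.00167) and Zelda (0.351, 0.0299) less frequent. Promoter summits had 34.7% GC and promoters without a peak 39.5%, so this control was not matched for GC either. Of the 9 motifs above the flank, 5 did not pass this control: motif 1 (odds ratio 1.10, adjusted exact p = 0.767), motif 6 (1.09, 0.69), CTCF (2.97, 0.0699), Su(Hw) (2.04, 0.13) and the homeodomain core (1.11, 0.103). Against the flank, 4 calls ended among the strongest 1922 peaks, those of motif 1, motif 6, CTCF and Su(Hw) (adjusted exact p of 0.109, 0.108, 0.108 and 0.219), and 3 among peaks matched in all replicates, those of motif 1, CTCF and ZIPIC (0.0669, 0.0669 and 0.0597). Su(Hw) also did not pass without replicate 3 (adjusted exact p = 0.0527). The 5 motifs that did not pass each passed under at least 1 of 7 alternatives. The initiator was less frequent at summits without replicate 2, within 100 bp of the summit and against a flank at 1000 bp (adjusted exact p of 0.0315, 0.015 and 0.0128), Pho against the latter flank (0.0349), and Zelda and Twist without replicate 1 (0.04 and 0.0254). The E-box was more frequent at summits without replicate 1 and within 100 bp of the summit (adjusted exact p of 0.0254 and 0.0339). No single fixed motif other than the homeodomain core and the initiator was in over 3.10% of summit windows.

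Short AT-rich sequences were more frequent at summits than in the flanks. The 10 7-mers with the smallest p on arms 2L, 3L and X consisted of A and T alone, were all more frequent at summits, and passed again on arms 2R, 3R and 4 (exact McNemar test, two-sided, adjusted p of at most 3.35e-08). On the latter arms TTTAAAA was at the summit and not in the flank of 212 peaks and the reverse held for 58. TTAAAAA gave 216 and 76, and TAAAATA 210 and 71. Summit windows had 34.1% GC and flank windows 44.3%, and such a difference by itself makes 7-mers of A and T more frequent at summits. The test on the other arms therefore cannot separate these sequences from base composition.

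The CG12942 gene (FBgn0033569; dm6 2R, 10894459 to 10897222, plus strand) had an optimal peak upstream of it. The peak (2R, 10894184 to 10894287, signal 170) had its summit 209 bp upstream of the CG12942 TSS and 135 bp upstream of the nearest TSS, that of the neighbouring gene cag. The matching peaks ranked 3981 in replicate 1, outside its top 3844, 425 in replicate 2 and 1228 in replicate 3. The flies also carried CG12942 as a transgene, and this extra copy of the gene was not adjusted for. A second optimal peak within 5 kb (2R, 10898991 to 10899394, signal 133) lay 133 bp upstream of the TSS of Polr2E and ranked 1118, 2022 and 3544 in the replicates.

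The authors called peaks on 2 genome builds, and the dm6 lists were as long or longer. The optimal set had 3844 peaks on dm6 and 3604 on dm3, 6.66% more on dm6. Replicates 2 and 3 had 30000 and 27870 peaks on dm6 against 27375 and 25001 on dm3, and the pooled lists 27271 and 24958. The dm3 lists of replicates 1, 2 and 3, the pooled and the optimal list include 64, 168, 220, 95 and 3 peaks on sequences outside the 6 arms, and the dm6 lists none except 1 peak on Y in replicate 3. Replicate 1 had 30000 on both, and 3 of the 6 replicate lists held exactly that number. The share on X was 17.6% in both optimal sets. Within the replicates it was 17.6%, 15.7% and 15.7% on dm6 and 17.7%, 15.8% and 15.7% on dm3.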

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

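The tests of explanations in this part were chosen after the results were seen. No group or condition differs among the samples, so no biological explanation was tested.

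Pooled dm6 peaks away from any optimal summit, used elsewhere only in counts per build and at the CG12942 locus, also lay at promoters more often than shifted ones. Of 23246 such peaks, 5660 (24.3%) were at promoters, against 11.4% on average and 12.5% at most in 100 circular shifts, and 1480 (6.37%) lay in coding sequence, against 13.9%.

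The concentration of optimal summits at promoters may come from a general enrichment of strongly transcribed or open sites, for which no library without the tagged protein was analysed here. Proteasome, respiratory chain, vacuolar ATPase, CCT and translation factor genes together had promoter peaks in 55 of 228 (24.1%), against 57 of 92 ribosomal protein genes (62.0%, Fisher's exact test, two-sided, p = 4.35e-10). These lists were set together after their shares had been seen, other housekeeping lists had higher shares (7 of 13 RNA polymerase II genes, 53.8%), and transcription was not measured. Of 290 tRNA genes, 12 (4.14%) had a summit within 500 bp, against 19.2% of protein-coding genes (Fisher's exact test, two-sided, p = 9.27e-14), and neither their transcription nor the placing of reads at them was measured. Neither value decides, and both explanations stay open.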

How the results depend on the processing

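The replicate overlap, rank correlation, promoter share, annotation classes, head-to-head promoters and X against autosomes kept their direction and their side of the threshold, or their count within 1.5 times, under each alternative run. All 10 k-mers passed on the test arms in each setting, but 3 of the 10 8-mers, and 1 of the 10 7-mers among peaks matched in all replicates, were more frequent in the flank. The mean overlap ranged from 65.1% with the top 7688 peaks to 77.4% without replicate 1, and the promoter enrichment from 3.01-fold with a window of 1000 bp to 6.91-fold with 250 bp. The share of optimal peaks matched in all replicates depends on the matching rule, moving from 63.5% to 57.8% within 100 bp, 65.3% for intervals sharing 1 bp, 45.6% for the stricter reciprocal overlap, 34.7% with the top 1922 peaks, 91.9% with the top 7688, and 70.5% to 74.9% with a replicate left out, where fewer replicates have to match. The number of gene lists past the threshold moved from 13 to 8 among the strongest 1922 peaks and to 7 among peaks matched in all replicates, and was 8 to 10 with a replicate left out, 8 of them without replicate 3. Lists above other genes fell from 7 to 4, 2 and 3 to 4 in these sets, and lists below them from 6 to 4, 5 and 5 to 6. With promoter clusters counted once 14 lists passed, 10 of them above other genes, and with a window of 1000 bp 15. The stricter and left-out sets hold fewer peaks, and those with a replicate left out also replace the optimal set by peaks shared by the top 3844 of 2 replicates, so neither the replicate nor the number of peaks was tested as the cause. The odds ratio of the synthetase list turned to 0.803 among the strongest 1922 peaks, and the cause was not tested. Chromosome 4 passed the threshold among peaks matched in all replicates (odds ratio 0.242), and with a replicate left out its odds ratio ran from 0.292 to 1.00; with 80 genes the cause was not tested. The promoter signal difference fell from 10.5 to 4.81 points among the strongest 1922 peaks, which were selected on signal and so span a narrower range of it. The fixed motifs past the threshold fell from 10 to 6 there, and the cause was not tested. Among single lists and motifs, 322 of 370 alternatives kept their side of the threshold, 33 lost the call and 14 gained it. A change of direction was counted only where the result or its alternative was called. The 322 therefore include uncalled lists and motifs whose direction changed, such as the proteasome (odds ratio 0.973, and 1.22 with promoter clusters counted once). The depth of the libraries is unknown.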

Other observations

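The tests of explanations in this part were chosen after the results were seen. Genes annotated as ncRNA and snoRNA had an optimal summit within 500 bp of an annotated transcript start less often than protein-coding genes (19.2%). The counts were 175 of 3261 ncRNA genes (5.37%, Fisher's exact test, two-sided, unadjusted p = 2.13e-99) and 9 of 269 snoRNA genes (3.35%, unadjusted exact p = 1.65e-14). Whether the annotated starts of noncoding genes have promoters of their own was not checked. Protein-coding genes had 19253 TSS positions for 13945 genes, and the number of starts per gene was not matched. Among snRNA genes the count was 6 of 32 (18.8%, unadjusted exact p = 1).

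The 8-mer CAACACTG was in 88 optimal summit windows and 8 flank windows, and 79 of the 88 summits (89.8%) were at promoters. It was noticed among all 8-mers over all arms, and 4 of 1902 other 8-mers compared had a summit-to-flank ratio as high. For CAACACTG, base frequencies of the windows gave an expected 6.63 summit and 8.90 flank windows and dinucleotide frequencies 8.89 and 12.6. The observed number at summits was 9.90 times the larger expectation (Poisson p times all 32896 8-mers = 8.65e-51), which argues against base composition. Promoters without a peak carried it in 74 of 10903 windows (0.679%), against 79 of 2008 promoter summits (3.93%, odds ratio 5.99, Fisher's exact test, two-sided, p = 1.73e-25). The 95 occurrences lay in 95 distinct stretches of 32 bp (100%), which argues against identical copies of one repeated element. Copies that differ by a single base also count as distinct, so diverged copies were not tested. A candidate explanation is that CAACACTG is part of a sequence that the tagged protein or a protein beside it recognises. However, 11 of its 88 summits were among the strongest 961 of the 3844 peaks, so it was rarer there than in the whole set. No binding experiment was analysed here.

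The low GC content of promoter summits was set against promoters in general. Promoter summits had 34.7% GC and promoters without a peak 39.5%, a difference of -4.84 points (permutation p = 1.00e-05, the smallest that 100000 permutations can give), so being a promoter is not enough to give the low GC content. A bias of the libraries towards AT-rich fragments could also lower it, and was not tested.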
